A study of Mus musculus with 12 samples.

How the data were processed

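Gene expression was measured in cultured mouse prostate cells with Illumina mouse arrays, on which each probe is a short DNA sequence carried by beads and its brightness reports the abundance of 1 transcript. Per the labels, the cells were prostate stem cells of the C57Bl/6 strain, grown either as an adherent layer or as spheroids. Total RNA was isolated with a miRNeasy kit and labelled as biotinylated cRNA with a MessageAmp kit, per the labels' protocols. The series held 12 arrays: 3 replicates and 1 pool of these replicates for each of 3 cultures, which were adherent mouse 1, adherent mouse 2 and spheroid mouse 1. The labels do not say whether replicates came from separate cultures or wells, so p-values measure only the spread between these samples, which may be technical. Only 1 spheroid culture was sampled.

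The authors deposited a non-normalized table with the mean bead intensity of 45135 probes on each array and a detection p-value per probe and array, per the file headers. The intensities were on a linear scale with the background still included. The scanner software was not given in the sources used here. In this table the header gives the same name to both remaining columns of adherent mouse 2, so these arrays are called unnumbered a and b, and no column was left out as belonging to other samples. The authors also deposited a table of normalized intensities of the same arrays on a linear scale, whose normalization method was not given in the sources used here. Each of its columns nearly kept the probe order of its own array (lowest Spearman correlation over all probes 0.9985). By this correlation array a matched the column of adherent mouse 2 replicate 2 (0.99992, against 0.843 for replicate 3). Array b matched that of replicate 3 (0.99984, against 0.843 for replicate 2). Its column medians were 126.2, 126.4, 127.0 and 125.0 for adherent mouse 1 (replicates 1 to 3, then the pool), 127.0, 124.7, 124.8 and 125.8 for adherent mouse 2, and 128.3, 127.9, 128.9 and 126.2 for spheroid mouse 1. These values carry no centring of genes, and how each array was scaled stays unknown.

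The non-normalized table was processed with limma 3.58.1 in R 4.3.3. The function neqc inferred each array's background from the detection p-values, subtracted it with a normal-exponential model, added an offset of 16 and quantile-normalized the log2 values over all 12 arrays. A probe was kept when its detection p was under 0.05 on all 3 replicate arrays of at least 1 culture, which 18950 probes met. Gene names came from the platform annotation supplied with the data: 34773 probes had 1 gene symbol, 18 had several and 10344 had none here. Of the annotated probes, 34695 matched a current mouse gene through the Entrez identifier, and 0 symbols changed. No gene was named from a probe with several symbols. Each gene was represented by its brightest passing probe, chosen over the 9 replicate arrays, which left 10112 genes, of which 3916 had more than 1 passing probe. For the genes called between spheroid and adherent culture, 1033 of 1680 other passing probes were called the same way, 638 were not called and 9 were called the opposite way. Between the adherent cultures 49 of 136 other probes were called the same way and 87 were not called.

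Between 43.1% and 49.1% of the probes were detected per array. The median raw signal was 129 to 150 against an inferred background mean of 124 to 143, and the brightest 10% of the probes began at 3.09 to 4.72 times the background. A log2 difference is on the scale after the offset, which understates changes of dim genes. Where a gene was undetected on every array of a culture, its fold is given as "at least", with the dim side set to the higher of its own value and the lowest signal of any detected probe on each array. Against both adherent cultures this bound is on their average.

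A linear model with a mean per culture was fitted to the 9 replicate arrays with limma (lmFit, then eBayes with an intensity trend). The pools were normalized along with the others but stayed out of the fit, since they hold RNA of the same replicates. The comparisons were spheroid against the average of the adherent cultures, spheroid against each adherent culture, and adherent mouse 2 against adherent mouse 1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a fold of at least 2. The fit and the calls were tested on simulated gene-level values, with 200 of 10112 genes changed in 20 simulations. These used each gene's mean over the adherent arrays and its fitted spread between replicates. For spheroid against both adherent cultures, 99.7% of genes changed by 1.5 on the log2 scale and 100% of those changed by 2 were recovered, with 0.15 false calls on average. For spheroid against adherent mouse 1 the shares were 98.9% and 100%, with 0.65 false calls. Normalization, the detection filter and the choice of probes were not part of this test, and no difference between cultures was simulated for unchanged genes. Both sizes of change lay past the 2-fold threshold, so the shares say little about changes near it.

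In all, 32 gene lists were fixed before the data were examined, together with the tests and most alternatives. They covered basal, luminal, secretory, stem, pluripotency, neuroendocrine, squamous, fibroblast and smooth muscle, epithelial-mesenchymal transition, endothelial, leukocyte and seminal vesicle genes, the G1/S and G2/M phases, hypoxia, cholesterol and fatty acid synthesis, Notch, Wnt, Hedgehog, TGF-beta, YAP/TAZ, integrin, basement membrane, junction, interferon, chemokine, retinoid, oxidative stress, unfolded protein, immediate early and p53 genes. Of 649 distinct members, 604 were named on the array and 422 were tested. Lists with at least 3 tested members (30 lists) were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The named genes were those with the largest changes (12 rises and 12 falls for spheroid against adherent culture, called against each adherent culture, and 8 of each between the adherent cultures), up to 4 members per list with the smallest adjusted p, and a set of identity genes. Of these, Ly6a was not analysed here, as no probe carried its name in the annotation used. Predicted genes without a proper symbol were skipped among the largest changes.

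The alternatives were other background corrections (none, or a normal-exponential fit with an offset of 50), cyclic loess or median scaling in place of quantile normalization, normalization without the pools, the authors' normalized values, no detection filter or one at 0.01, the mean of a gene's probes, a threshold on the adjusted p alone or limma's treat against a fold of 1.5, no intensity trend, the pools as an extra sample of each culture, each replicate left out in turn, the replicate number as a block, and 3 other units of replication. Alternatives added after seeing the data were the replicate block on the authors' values, the mouse 1 arrays fitted alone, and camera with an intensity trend. Gene order along chromosomes came from the GRCm38.p6 annotation and was used only to find neighbouring genes. Figures were drawn with matplotlib.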

Results

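Mouse prostate stem cells were profiled on 12 arrays after growth as an adherent layer or as spheroids, which are balls of cells. Adherent cells of mouse 1, adherent cells of mouse 2 and spheroid cells of mouse 1 were each represented by 3 replicate arrays, and 1 further array per culture held a pool of those replicates. Between 43.1% and 49.1% of the 45135 probes were detected on each array, and 10112 genes were tested. The brightest 10% of the probes began at 3.09 to 3.24 times the background on the spheroid replicate arrays (3.63 on their pool) and at 3.82 to 4.72 times on the adherent arrays, so this measure of signal moved with the main comparison. Log2 values correlated across these genes at 0.989 to 0.991 within the spheroid arrays, at 0.993 within adherent mouse 1 and at 0.975 to 0.994 within adherent mouse 2. They correlated at 0.971 to 0.981 between the adherent cultures and at 0.843 to 0.860 between spheroid and adherent arrays (correlations are across genes, which are not independent replicates).

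The first principal component, with 82.8% of the variance, separated spheroid from adherent arrays, and the second, with 6.82%, separated the adherent cultures. Adherent mouse 2 replicate 1 lay at 6.18 on the second component, between the adherent mouse 1 arrays and the 2 other replicate arrays of its own culture at 25.9 and 31.5. The pool of adherent mouse 2 lay at 11.5. The pool arrays differed from the log2 of their replicates' mean with an SD over genes of 0.23 for adherent mouse 1, 0.28 for adherent mouse 2 and 0.26 for the spheroid culture.

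**Figure D1:**
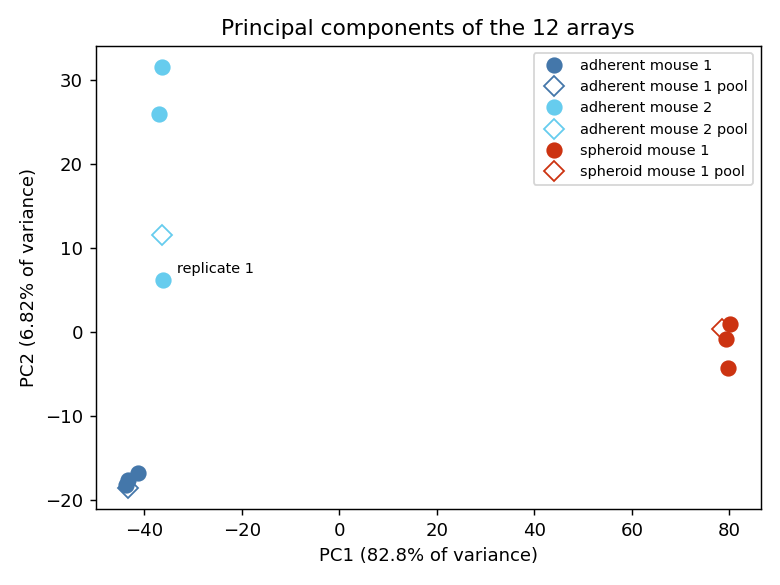
Scores of the 12 arrays on the first 2 principal components of the log2 values of all tested genes, with the share of variance on each axis. Filled circles are replicate arrays and open diamonds are pool arrays, coloured by culture; spheroid arrays lie at 78.5 or above on the first component and all adherent arrays at -36.2 or below.

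The main comparison set spheroid against adherent culture, the contrast the study's design names. Several of the 12 named genes with the largest rises in the spheroid culture encode parts of the cornified envelope, the protein shell of squamous epithelium. Cnfn (cornifelin) rose by 7.94 ± 0.10 on the log2 scale (SE, 9 arrays), Sprr2d (a small proline-rich envelope protein) by 8.48 ± 0.18, and Lce3f (a late cornified envelope protein) was at least 219-fold higher. Rptn (repetin, an envelope precursor) was at least 248-fold higher than in adherent mouse 1, where it was undetected, and 101-fold higher than in adherent mouse 2. Wfdc12 (a whey acidic protein family protease inhibitor) was at least 741-fold higher, Krt23 (an epithelial keratin) at least 695-fold, and Lcn2 (lipocalin 2, which binds bacterial siderophores) at least 197-fold. Slpi (a secreted inhibitor of leukocyte proteases) rose by 7.93, Defb14 (a beta-defensin) by 8.22, and Crct1, Clca3b and Tmem45b by 8.11, 7.77 and 7.69. Clca3b was detected on 2 of 3 adherent mouse 1 and 1 of 3 adherent mouse 2 arrays, and Sprr2d and Crct1 on 2 of 3 adherent mouse 2 arrays, so their adherent side lay near background.

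Among the 12 named genes with the largest falls, Thbs2 (thrombospondin 2, a matrix glycoprotein) was at least 53.7-fold lower in the spheroid culture, Ptn (pleiotrophin, a secreted growth factor) had a log2 difference of -5.81 ± 0.10 and Fn1 (fibronectin) of -5.43 ± 0.21. Vim (vimentin, the mesenchymal intermediate filament) had a log2 difference of -5.35 and was detected on 2 of 3 spheroid arrays. Acta2 (smooth muscle actin) had one of -4.00, with adherent signals near the top of the array's range, where differences are compressed. The difference was -5.45 for Emp3, -4.25 for Thsd4 and -4.17 for Nectin3 (an adhesion molecule, detected on 2 of 3 spheroid arrays). Sgo1 (shugoshin, which protects centromeric cohesion) was at least 19.96-fold lower, and Kif15 (a mitotic kinesin, detected on 2 of 3 spheroid arrays) had a log2 difference of -4.21, C1qbp (a mitochondrial matrix protein) of -4.42 and H2ac22 (a histone H2A) of -3.92. All 24 of these genes had adjusted p-values (limma, Benjamini-Hochberg) of 1.23e-08 or below.

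By the limma test 2684 of 10112 genes were called, 1327 of them higher and 1357 lower in the spheroid culture, and 230 of the higher and 73 of the lower ones differed at least 8-fold. Every gene past the 2-fold threshold also passed the adjusted p, so the fold decided the count. Median scaling gave 881 higher and 2327 lower genes and cyclic loess 1462 and 1061, so the balance of directions depended on the scaling. With no background correction 1290 genes were called, with a fit at an offset of 50 the count was 1702, and on the authors' normalized values it was 1478. The pools gave the same sign for 2683 of the 2684 genes and a fold of at least 2 for 2329.

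Against each adherent culture on its own, the spheroid culture had 2786 called genes (mouse 1, 1360 higher and 1426 lower) and 2705 called genes (mouse 2, 1330 higher and 1375 lower). Of these, 2227 were called in the same direction against both cultures, 1123 higher and 1104 lower, and 3 were called in opposite directions. Independent lists of these sizes would share 179 higher and 194 lower genes. The log2 differences of both comparisons correlated at 0.944 across genes with a covariance of 1.37, against 0.5001 and 0.0167 for simulated unchanged groups that share the spheroid arrays. With 3 spheroid arrays the shared side could not be split into parts of at least 2, so part of the excess may come from the shared arrays. The simulated groups held no difference between cultures, so any trait of the single spheroid culture would also raise the correlation and covariance.

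Basal identity genes of the prostate were detected on every replicate array. Krt5 and Krt14 (the keratin pair of basal epithelial cells) differed between spheroid and adherent culture by -0.06 and 0.10 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.702 and 0.0889), with Krt14 near the top of the array's range, where differences are compressed. Trp63 (the basal transcription factor p63) had a log2 difference of -0.56, within the 2-fold threshold (adjusted p = 4.35e-05, limma), and Itga6 (an integrin chain of basal cells) of 0.18 (adjusted p = 0.357, limma). Of the simple-epithelial keratin pair, Krt18 fell by 1.42, while Krt8 had a log2 difference of -0.96 and stayed within the 2-fold threshold. Against adherent mouse 2 alone Krt8 was called lower (-1.07), and against adherent mouse 1 alone it was not (-0.84). Over the basal list of 18 tested genes, 2 rose and 3 fell and the list was not called (adjusted p = 0.939, limma camera), with log2 differences of 2.73 for Krt15 (a basal keratin), 1.19 for Tns4, -1.92 for Sncg and -1.56 for Snai2 (the transcription factor Slug).

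Squamous differentiation genes rose together: against the average of the adherent cultures 22 of 24 tested members rose and 0 fell, with a median log2 difference of 3.19 (2.97 with undetected members at their bounds). Against adherent mouse 1 alone 22 rose and 0 fell, and against adherent mouse 2 alone 20 rose and 1 fell, which was Sprr2a1 at -1.22 (a small proline-rich envelope protein, named here after its value was seen). The adjusted p of limma's camera was 1.99e-11, and 0.00969 with an estimated correlation. S100a8 (a calcium-binding alarmin of stressed epithelium and leukocytes) was at least 73.2-fold higher and Krt16 (a keratin of activated epidermis) rose by 4.27 ± 0.09. The mean log2 signal of the list's genes was 10.58 ± 0.05 in the spheroid culture, 6.85 ± 0.08 in adherent mouse 1 and 7.36 ± 0.05 in adherent mouse 2 (SD, n = 3 arrays each).

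Cell cycle genes fell together. Of 22 tested genes of the G1/S phase 22 fell, with a median of -2.69 (limma camera adjusted p = 7.93e-11, and 0.00813 with an estimated correlation), among them Mcm5 and Mcm4 (subunits of the replicative helicase) at -3.41 and -2.70, Uhrf1 (which maintains DNA methylation at replication) at -3.23 and Ung (uracil-DNA glycosylase) at -3.29. A further Ung probe differed by -0.38 and was not called. Of 15 tested genes of the G2/M phase 13 fell and 0 rose, with a median of -3.10 (adjusted p = 5.46e-08 by limma camera, and 0.00969 with an estimated correlation). Its leading members were Cdc20 (activator of the anaphase-promoting complex) at -3.62, Birc5 (survivin) at -3.30, Aurka (a mitotic kinase) at -3.58 and Bub1b (a spindle checkpoint kinase) at -3.45.

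**Figure D2:**
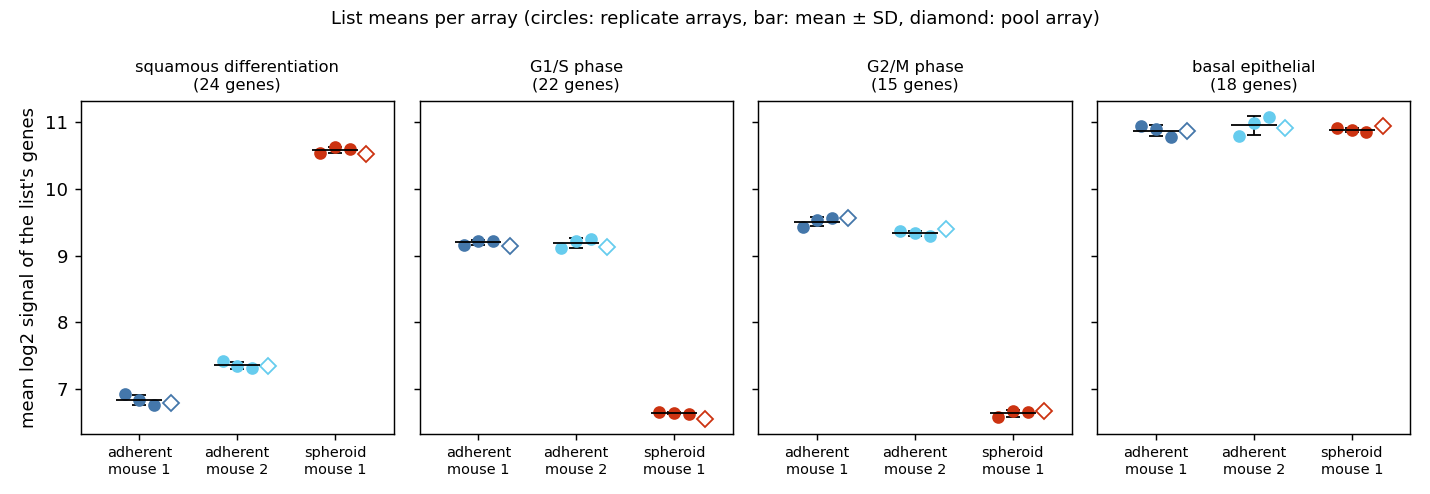
Mean log2 signal of the tested genes of 4 lists, in 1 panel per list, for each array of the 3 cultures; circles are replicate arrays, the bar and whiskers their mean and SD (n = 3), and diamonds the pool arrays. The squamous list lies at 10.58 in the spheroid culture against 6.85 and 7.36 in the adherent cultures, the G1/S list at 6.65 against 9.20 and 9.19, the G2/M list at 6.64 against 9.51 and 9.33, and the basal list at 10.88 against 10.87 and 10.95.

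A further 7 lists were called higher by limma's camera at the preset correlation, and each lost the call with an estimated correlation. Immediate early genes, which respond within minutes to signals, held 11 rises and 1 fall among 19 (limma camera adjusted p = 0.000678, and adjusted p = 0.189 with an estimated correlation), led by the phosphatases Dusp1 and Dusp4 at 4.84 and 5.28, with Ier3 and Klf6 at 1.98 and 1.71. Luminal epithelial genes held 7 rises and 1 fall among 11 (limma camera adjusted p = 0.00256, and adjusted p = 0.189 with an estimated correlation), with Krt19 at 5.78 (detected on 1 of 3 adherent mouse 1 arrays), Elf3 (an epithelial ETS factor) at 4.56 and Cldn4 (a tight junction claudin) at 1.87. The fall was that of Krt18, and Krt8, also a member, had a log2 difference of -0.96. Of 14 prostate secretory and androgen-responsive genes named on the array, only 6 passed the detection filter and were tested. These 6 held 4 rises (limma camera adjusted p = 0.00488, and adjusted p = 0.162 with an estimated correlation). The rises were Fkbp5 (a chaperone induced by steroid receptors) at 5.43, Tmprss2 (a membrane serine protease, detected on 2 of 3 adherent mouse 1 arrays) at 2.58, Acpp (prostatic acid phosphatase) at 1.19, and Klk1 (a kallikrein), which was at least 3.55-fold higher.

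Retinoid and aldehyde genes held 6 rises among 9 (limma camera adjusted p = 0.00629, and adjusted p = 0.243 with an estimated correlation), with Aldh1a3 (which makes retinoic acid) at 4.79, Aldh3a1 at 1.65, Aldh3b2 at 3.65 (detected on 1 of 3 adherent mouse 1 and 2 of 3 adherent mouse 2 arrays) and Lrat (which esterifies retinol) at least 4.68-fold higher. Junction genes held 8 rises and 2 falls among 20 (limma camera adjusted p = 0.00335, and adjusted p = 0.0835 with an estimated correlation), with Cldn1 at 5.20 (detected on 2 of 3 adherent mouse 2 arrays), Tjp3 at 3.74 and Cdh3 (P-cadherin) at -1.28. Interferon-response genes held 9 rises and 1 fall among 19 (limma camera adjusted p = 0.00268, and adjusted p = 0.0938 with an estimated correlation), with B2m at 1.76, Gbp2 at 2.22, Usp18 at 2.35 and Irf9 at 2.07. Chemokine and NF-kappaB genes held 6 rises and 2 falls among 17 (limma camera adjusted p = 0.00335, and adjusted p = 0.0835 with an estimated correlation), with Cxcl1 at 2.51, Cxcl16 at 1.48 and Nfkbiz at 1.18. Adjusted over the list alone, the counts of every list were the same as over all genes. For the junction, interferon, chemokine and retinoid lists, 9, 16, 5 and 12 of the 84 ways to pick 3 of the 9 arrays gave a camera p as small as the real one.

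The remaining lists with at least 3 tested genes were not called (adjusted p of 0.0697 to 0.939, limma camera). Stem and progenitor genes went both ways, with 5 rises and 4 falls among 13: Psca (prostate stem cell antigen) and Ly6d rose by 5.46 and 3.01 and Ezh2 (a Polycomb methyltransferase) had a log2 difference of -1.59 (-0.62 by another of its probes). Of 6 tested pluripotency genes Klf4 rose by 1.95 and Sox2 fell by 1.69 (a second Sox2 probe gave -0.25), while Myc had a log2 difference of -0.98. Neural cell adhesion molecule Ncam1, the lone neuroendocrine gene tested (1 of 12), had a log2 difference of -2.17, and its other probes gave -0.06 and -0.81. No seminal vesicle gene passed the filter. Endothelial genes held 0 rises and 0 falls among 3, and leukocyte genes 2 rises among 5, which were Cd14 (an endotoxin coreceptor) at 2.81 and Cd52, at least 2.23-fold higher.

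Mesenchymal and matrix lists held more falls than rises, without passing the list test. Fibroblast and smooth muscle genes held 3 falls among 5 (adjusted p = 0.0698, limma camera), namely Acta2, Fbln1 (fibulin 1) at -2.11 and Actg2. Genes of the epithelial-mesenchymal transition held 6 falls and 1 rise among 12 (adjusted p = 0.0697, limma camera), with Sparc (a matrix glycoprotein) at -3.36 and Tgfbi at least 15.2-fold higher than in adherent mouse 1, where it was undetected, and 12.1-fold higher than in adherent mouse 2. Basement membrane genes held 6 falls and 2 rises among 18, with Tnc (tenascin C) at -3.76, Hspg2 (perlecan) at -2.27 and Col18a1 at -1.25. Integrin genes held 4 falls and 1 rise among 16, with Zyx, Ilk (integrin-linked kinase, -0.95 on another probe) and Itgb1 at -1.65, -1.48 and -1.18 and Itgb6 at 2.13.

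Signalling lists were mixed. Genes of TGF-beta and BMP signalling held 5 rises and 5 falls among 17, with Id2 and Id1 (dominant-negative helix-loop-helix proteins) at 4.40 and 4.14 and Id4 at -2.71. Notch genes held 2 rises (Nrarp 1.51, Notch4 1.11) and 2 falls (Dll1 -1.79, Jag2 -1.33) among 9. Notch4 was detected on 1 of 3 adherent mouse 1 and 2 of 3 adherent mouse 2 arrays, and Dll1 on 2 of 3 spheroid arrays. Wnt genes held 3 of each among 12, with Wnt4 at 1.69 and the receptors Fzd7 at -1.93 and Fzd2, at least 2.90-fold lower. Hedgehog genes held 3 falls among 8 (adjusted p = 0.0697, limma camera), with Gli3 at -1.55 and Smo at -1.02. Other probes of Gli3 and Smo gave -0.77 and -0.23, and the call of Smo was lost without adherent mouse 2 array b (-0.97) or spheroid replicate 2 (-0.89). YAP/TAZ targets held 4 falls and 1 rise among 17, with Axl at -1.66, against 0.45 on another of its probes.

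Among metabolic and stress lists, hypoxia and glycolysis genes held 7 rises among 22, with Ndrg1 at 3.38, Pfkfb4 at 2.90 and P4ha2 at 1.75. Oxidative stress genes held 7 rises among 23 (adjusted p = 0.0817, limma camera), with Hmox1 (heme oxygenase 1) at 3.47 and Gsta4 at 2.21. Unfolded protein genes held 6 rises and 4 falls among 23, with Herpud1 at 2.89 and the serine and one-carbon enzymes Phgdh, Shmt2 and Mthfd2 at -2.28, -2.01 and -1.76. Fatty acid genes held 1 rise and 4 falls among 13, with the desaturases Fads1 (-0.86 on another probe) and Fads2 at -2.78 and -2.71, and cholesterol genes held 0 of each among 18. Targets of p53 held 4 rises and 3 falls among 19, with Sesn1 at 2.36, Gtse1 at -2.76, Fas at -3.02 and Ddit4l at -2.22.

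The adherent cultures of mouse 2 and mouse 1 were compared as a yardstick for how far separate cultures of the same kind differ. The chemokine gene Ppbp was 5.29 ± 0.14 higher in mouse 2 on the log2 scale (SE), the secreted protein gene Wfdc2 4.88 higher, Krt19 3.93 higher, Ildr1 2.82 higher and Msln (mesothelin) 2.80 higher. Wfdc2 and Krt19 were each detected on 1 of 3 adherent mouse 1 arrays, Slurp1 on 2 of 3, and Rangrf, named below, on 1 of 3 adherent mouse 2 arrays, so their lower side lay near background. Slurp1 (a Ly6 family protein of keratinocytes) rose by 2.48, Adh7 (an alcohol dehydrogenase of retinol oxidation) by 2.46, and Scara5 (a ferritin receptor) by 2.51, though a second Scara5 probe gave -0.07. Pak3 (a p21-activated kinase) was at least 19.1-fold lower in mouse 2, and Cd200 (an immune-inhibitory surface protein), Rangrf, Ptp4a3 (a phosphatase), Gstk1, Glipr1, Gas6 (a ligand of Axl-family receptors) and Lgals7 (galectin 7) had log2 differences of -3.26, -3.23, -2.69, -2.69, -2.50, -2.39 and -2.31 (-0.87 on another Lgals7 probe). All 16 had adjusted p-values of 3.20e-05 or below (limma, Benjamini-Hochberg).

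In all, 249 genes were called between the adherent cultures (limma), 143 higher and 106 lower in mouse 2, and 42 of the 2684 genes of the main comparison differed as much between the adherent cultures as between spheroid and adherent culture. Without adherent mouse 2 replicate 1, the array that stood apart, 376 genes were called. Median scaling gave 236 higher and 67 lower genes, no background correction gave 51 genes and the authors' values gave 63. Squamous differentiation genes held 6 rises and 0 falls among 24 in mouse 2, with Cnfn at 2.00, Sprr3 at 1.82, Dmkn at 1.37 and Krt13 at 1.32 (0.21 on a second Krt13 probe), and limma's camera gave an adjusted p of 5.50e-05, and adjusted p = 0.219 with an estimated correlation. The luminal list (1 rise, Krt19) and the integrin list (no gene called) were higher in mouse 2 at an adjusted p of 0.0398 (limma camera), and adjusted p = 0.511 with an estimated correlation for both. The number of called lists ran from 1 to 5 when single arrays were left out, with 1 without adherent mouse 1 replicate 3 or adherent mouse 2 array b, and 2 without array a or spheroid replicate 3. The basement membrane list (1 rise) was called at an adjusted p of 0.0398 (limma camera), and adjusted p = 0.538 with an estimated correlation. Oxidative stress genes, not called as a list, held 4 rises and 2 falls among 23, with the glutathione transferases Gsta2, Gsta1 and Gsta4 at 2.11, 1.97 and 1.81 and Gstm2 at -1.23 (-0.92 on another probe). Of the immediate early genes Egr1 and Jun had log2 differences of -2.07 and -1.06, and both cell cycle lists held 0 called genes.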

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

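The tests of this part were chosen after the results were seen, except the numbers of genes and of lists called over other splits of the arrays; the splits per single list were chosen afterwards. Of the 3040 tested probes that carry no gene name here, 547 passed the same thresholds between spheroid and adherent culture (268 higher, 279 lower), and 52 passed between the adherent cultures (21 higher, 31 lower). They stand out only as signal outside the gene tests, with no explanation tested.

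Picking any 3 of the 9 arrays in place of the spheroid ones gave as many calls in 1 of 84 splits, the real one. In a fit of 2 groups it called 2673 genes, and the others at most 89 (the split that sets adherent mouse 1 apart). These splits exchange arrays between cultures, although the 3 spheroid arrays are replicates of a single culture. They show that the spheroid arrays stand apart together. With 1 spheroid culture they cannot exclude chance differences between cultures. For the genes called against each adherent culture, 3 of 100 drawn splits gave as many as the real 2227. The highest other had 2410, and both other splits that gave as many kept the 3 spheroid arrays together and only mixed the adherent ones. Splits that parted the spheroid arrays reached at most 27. This again shows that the spheroid arrays stand apart together, and cannot exclude chance differences between cultures. For the single comparisons 10 splits are too few for a share under 0.05: 1 of 10 splits reached the real count of 2786 (mouse 1), 2703 (mouse 2) and 232 (adherent cultures), and the highest other count was 0 in each.

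The number of called gene lists fared worse. Between spheroid and adherent culture 9 of 84 splits called as many lists as the real 10, with a highest other of 11, so chance assignment is not excluded for the number of lists. Among single lists, the squamous, G1/S, G2/M and secretory lists had the smallest camera p in the real split (1 of 84 splits each). The luminal and immediate early lists were reached in 3 of 84. These shares carry the same limit of 1 spheroid culture. Between the adherent cultures 8 of 10 splits called as many lists as the real 1 in a fit of those 6 arrays, with a highest other of 3, and 10 splits are too few for a share under 0.05.

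The rise of squamous differentiation genes in the spheroid culture was set against technical causes. The lowest median of the list over 6 scalings, the authors' among them, was 2.04 on the log2 scale, which speaks against normalization as the whole cause. Leukocytes, which also express S100a8, would bring their abundant transcripts, yet 3 of 14 leukocyte markers named on the array were detected on all 3 spheroid arrays and 10 on at most 1. Members outside the Sprr, Lce, S100, keratin and kallikrein families had a median of 3.35 (8 genes, SE of their mean 0.96). This argues against cross-hybridisation within these families as the whole cause. Members were sorted by gene name alone, so relatives of the 8 genes were not checked. For the 16 family members cross-hybridisation cannot be told apart from single rises, since probe sequences were not used. A trait of the single spheroid culture sampled (1) also stays open, and a biological effect of growth form remains an untested hypothesis.

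The fall of cell cycle genes was treated alike. Over the 6 scalings the highest median of the G1/S and G2/M lists was -1.69, against normalization as the whole cause. Dilution of basal cells by cells without basal transcripts would lower basal markers by as much. The median of the basal list was instead 0.065 (SD over members 1.08, and -0.28 to 0.28 over the scalings). Cells that keep basal transcripts but do not cycle would leave that list unchanged, so it cannot decide about them. What remains open is a larger share of such cells, slower growth, a cell density effect or a trait of the single culture, none of which was tested.

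Adherent mouse 2 replicate 1 differed at least 2-fold from the mean of the other arrays of its culture at 326 genes. An error of that array alone would leave the pool array, made from the same replicates, at 0 on the way from the other arrays to replicate 1, but its median position was 0.508 (95% bootstrap interval 0.471 to 0.557), which also lies above the 0.416 that an equal mix predicts. A wrongly labelled sample of adherent mouse 1 would lie at about 1 between array b and mouse 1. Replicate 1 instead lay at 0.294 (0.242 to 0.386) on 315 genes. These were first chosen with other arrays, then kept only with a minimum difference between the arrays that define positions 0 and 1. Admixed mouse 1 RNA as the whole cause is argued against by 30 genes that lay at least 2-fold outside the range of mouse 1 and the other arrays, against at most 6 on any other adherent array. A real difference between the replicate samples stays open, though with an equal mix it alone does not predict the pool's position. A slide or processing difference shared by some of these arrays also stays open, since the column names give no slide. No biological explanation was tested.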

How the results depend on the processing

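Alternatives named as added here were chosen after seeing the data. Counts are in the order both adherent cultures, mouse 1, mouse 2, adherent cultures, and each culture (2684, 2786, 2705, 249 and 2227 as reported). Without background correction they were 1290, 1363, 1313, 51 and 1098, with an offset of 50 they were 1702, 1764, 1731, 82 and 1415, and on the authors' values 1478, 1539, 1502, 63 and 1242. Without background correction 6437 genes passed the adjusted p alone for both adherent cultures, against 6439 as reported. All 1290 genes past 2-fold there were called, so smaller folds and not the p-values lowered that count. For the other settings the cause was not tested. Nearly all calls of these settings were among those reported (1290 of 1290, 1701 of 1702 and 1475 of 1478 for both adherent cultures). The adjusted p alone called 6439, 5950, 6064, 1350 and 5022, and treat against a fold of 1.5 called 108 between the adherent cultures.

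The fold threshold decided nearly every call: 2684 of 2684, 2786 of 2786, 2705 of 2707 and 249 of 254 genes past 2-fold also passed the adjusted p. Settings that only change p-values therefore say little through these counts. By the adjusted p alone, the main comparison had 6439 genes, 3517 on culture means (1 residual degree of freedom), 5029 with culture as a random block (correlation 0.225) and 5925 with the adherent arrays as 1 group. Their counts with the fold were 2626, 2666 and 2673.

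Same-numbered replicates showed no clear positive correlation of their deviations (-0.040 to 0.070 in the scanner table for the mouse 1 cultures, and -0.254 to 0.114 over 9 pairs of the authors' values, 1 above 0.1). Adherent mouse 2 and spheroid replicates numbered 1 and 3 correlated at -0.254 and -0.229 on the authors' values. No positive pairing by number was seen, but these values do not establish that the samples are unpaired. By the header's numbers the replicate block was run for mouse 1 (2786 genes) and, as an added alternative, on the authors' values for all comparisons (1478, 1539, 1502, 63 and 1242, the counts without the block). The replicate numbers that arrays a and b match were not used for a block on the non-normalized values. By the adjusted p alone the block on the authors' values gave 6312 genes against 6431 without it for both adherent cultures, and 1139 against 1437 between the adherent cultures. A slide block was not run, since the column names give no slide.

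Median scaling moved the median of all genes to -0.35 and the share of higher calls from 49.4% to 27.5% (3208 genes) for both adherent cultures, from 48.8% to 31.9% for mouse 1, from 49.2% to 23.1% for mouse 2, from 50.4% to 27.5% for each culture, and from 57.4% to 77.9% between the adherent cultures, where the median moved to 0.17. The cause was not tested. Changes are best read relative to that shift.

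Leaving out 1 array gave 2676 to 2725, 2786 to 2818, 2667 to 2854, 219 to 376 and 2188 to 2258 genes, with 376 without adherent mouse 2 replicate 1. The list counts ran from 10 to 11 (10 reported) and from 1 to 5 (4 reported between the adherent cultures, with 1 without adherent mouse 1 replicate 3 or array b, and 2 without array a or spheroid replicate 3). Estimated correlation left 3 and 0 lists and fry, which does not compare with other genes, called 28 and 12. For both adherent cultures no background correction called 11 lists (8 higher and 3 lower), the 10 reported ones among them. Lists reported as not called can thus gain a call with other settings. Between the adherent cultures cyclic loess and median scaling each left 1 list and no detection filter 2. The squamous, G1/S and G2/M lists kept their call in 23 of 23 alternatives and the other 7 in 22 of 23. The main list test has no intensity trend, and camera with one, added later, called 11 and 4. Of 6346 alternative values of named genes, 6112 kept the call or its absence, 199 lost it, 35 gained it and 0 turned direction. Signal over background limits what dim genes can show, and at the brightest 10% it was lower on every spheroid array (3.09 to 3.63) than on any adherent array (3.82 to 4.72).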

Other observations

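The tests of this part were chosen after the results were seen. Genes higher in the spheroid culture lay in runs along 3 chromosomes. Among windows of 15 neighbouring tested genes, the fullest held 13 called genes, on chromosome 3: S100a7a, S100a8, S100a9, Pglyrp4, Lor (loricrin) and 8 Sprr genes, all part of the epidermal differentiation complex. A window on chromosome 7 held 12 kallikrein genes, secreted serine proteases of skin, prostate and salivary gland, among them Klk7, Klk8, Klk10, Klk11, Klk13 and Klk14. A window on chromosome 15 held 10, including Psca, Slurp1, Slurp2, Lynx1, Ly6d and Ly6c1 of the Ly6 family, which encodes small surface and secreted proteins.

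Shuffling gene order over the 10101 placed genes gave at most 9 called genes in the fullest window in 95% of 1000 shuffles. Chance order is thus argued against for the 13 higher genes. The fullest window of any shuffle held 11, so the chromosome 15 window with 10 lay past the 95% limit but within the range of the shuffles. Genes lower in the spheroid culture reached at most 7 in a window, within that limit of 9, and no run was found. The runs hold related genes, whose probes may report each other's transcripts, so 13 neighbours need not be 13 separate changes, and whether the runs reflect shared regulation was not tested.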
